A study of Mus musculus with 8 samples.

How the data were processed

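The study measured RNA by sequencing in hand-picked pancreatic islets of 8-week-old mice, 4 wild type and 4 lacking snoRNAs U32a, U33, U34 and U35a of the Rpl13a gene. Per the labels' protocols, total RNA was prepared with TRIZOL and treated with DNase, and libraries were made with the SeqPlex RNA kit, which amplifies randomly primed cDNA. Selection of polyadenylated RNA and strand are not given in the sources used here. The sample descriptions name the same run and lane with different indexes for all 8 libraries, so the labels hold no sequencing batch to separate. Each library comes from a different mouse, per the labels' protocols.

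The submitters' processing notes name STAR 2.4.1, an aligner, Partek, and the mouse build mm9. Their roles and the gene annotation are not given in the sources used here. The first deposited table holds estimated counts per gene: 9.98 to 12.4% of the values in a library were not whole within 0.01, and all values were rounded to whole numbers before any count test. The second deposited table holds RPM (reads scaled to a total of 1e+06) made by the authors: each value less an offset of 0.0001 was the count divided by 1 constant per library. Those constants correspond to 37.3 to 67.5 M reads per library, larger than the assigned totals, which were 52.5 to 60.9% of them. The same 24469 genes stand in both tables, and every column was matched to a sample by its title. Genes that share reads with a near-identical copy, such as the kallikrein, hemoglobin and insulin genes, may have counts split between copies by the authors' counting.

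Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by genotype, a robust quasi-likelihood F-test of knockout against wild type with no other term, and Benjamini-Hochberg adjustment over the 13617 genes kept, with a threshold of 0.05. The common biological coefficient of variation was 0.239. CPM values are counts over TMM-scaled library sizes of the genes kept, and standard errors of log2 fold changes come from the F statistic. Lists of genes for islet cells, ribosomes, metabolism, stress and the other cell types of the pancreas were written before the data were examined, 37 in all. The 32 lists with at least 5 tested members were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and adjustment over lists, beside camera with an estimated correlation and fry. Shares of counts were compared with exact two-sided permutation tests of 70 splits, whose smallest p is 0.0286. Genes are named by a rule also set beforehand: the host gene and the targeted snoRNAs, the 6 hormone genes, every gene past FDR 0.05 when fewer than 20 pass together with the 5 higher and 5 lower genes of smallest p that do not, and up to 3 members per list past FDR 0.05 or else up to 2 of smallest p. A gene that this rule picked is not reported here and was not replaced. A few other genes are named with the remark that they were chosen after their values were seen.

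The fit was tested on simulated counts drawn from the means, sizes and dispersions of these 8 libraries, with 13670 genes kept. It recovered 100% of 4-fold changes, 79.1% of 2-fold changes and 19.4% of 1.5-fold changes, with 8 false genes among 140 calls. The simulated genes varied independently, without the variation that genes of the real libraries share. Changes were planted only in genes above a limit of expected counts. The recovered shares may therefore be too high for the real libraries. The smallest shift between any 2 libraries was 26.4 times sampling noise (chi-square per degree of freedom), so no 2 libraries analysed here were copies. Intervals and floors of counts cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

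GC content came from GENCODE M21 transcripts of GRCm38, matched by symbol for 98.5% of genes. Gene order came from a RefSeq gene table, matched by symbol for 99.5%. Since GRCm38 is not the submitters' mm9, no coordinates are printed. Alternatives fixed before the data were examined were other normalizations, filters, tests (DESeq2 1.42.0, limma-voom with and without library weights, limma-trend on log2 of the authors' normalized values plus 1), library sizes without acinar and hormone genes, the replicate number as a block, the acinar share as a covariate, a dispersion without robust estimation, an FDR of 0.10, and each library left out in turn. Alternatives chosen after seeing the data were a lowess GC trend per library (span 0.3), high or low Xist counts (limit 1000) as a covariate, the 5 libraries with low Xist alone, library sizes without Rn45s, Lars2 and Mir6236, and combinations without wild-type replicate 1.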

Results

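RNA was sequenced from pancreatic islets, the hormone-secreting cell clusters of the pancreas, which had been picked by hand from 8-week-old mice. The 8 libraries came from 4 wild-type C57BL/6 mice and 4 mice on that background that lack the box C/D snoRNAs U32a, U33, U34 and U35a, which are encoded in introns of the ribosomal protein gene Rpl13a. Box C/D snoRNAs guide 2'-O-methylation of ribosomal and other RNAs. The count table listed 24469 genes, and 2.12e+07 to 4.11e+07 counts per library were assigned to them. The ribosomal RNA precursor Rn45s took 36.7 to 41.3% of the assigned counts, and Lars2, annotated as a mitochondrial tRNA synthetase gene, took 5.0 to 6.47%. Whether the counts on Lars2 come from its messenger RNA or from ribosomal RNA was not tested. The comparison asked which islet transcripts differ in level between mice without and mice with these snoRNAs.

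Of the targeted snoRNAs, U32a (Snord32a) had 5, 1, 1 and 2 counts in wild-type replicates 1 to 4 and 0 in each of the 4 knockout libraries. U33 (Snord33) had 6 counts over the wild-type libraries and 0 over the knockout libraries. U34 (Snord34) and U35a (Snord35a) had 0 counts in all 8 libraries and say nothing on the labels. The 4 snoRNAs together had 15 counts in wild type and 0 in knockout, a separation that reached the smallest p an exact two-sided permutation test of 70 splits allows (p = 0.0286). A count of 0 allows up to 3 counts in a library, a limit that covers counting error only, so no fold change was computed. The other 65 Snord genes in the table had 241 counts in wild type and 175 in knockout (exact permutation p = 0.343). Among them Snord35b had 4 counts in wild type and 0 in knockout (exact permutation p = 0.143). The host gene Rpl13a was measured at 105 ± 26 CPM (counts scaled to a library size of 1e+06, with TMM) in wild type and 97.8 ± 8.16 CPM in knockout (mean ± SD, n = 4 each). Its log2 fold change was -0.10 ± 0.16 (SE), with an adjusted p of 0.760 in edgeR's quasi-likelihood test. Without wild-type replicate 1, which had the highest Rpl13a level, the estimate was 0.057, and with the acinar share as a covariate it was -0.25.

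**Figure D1:**
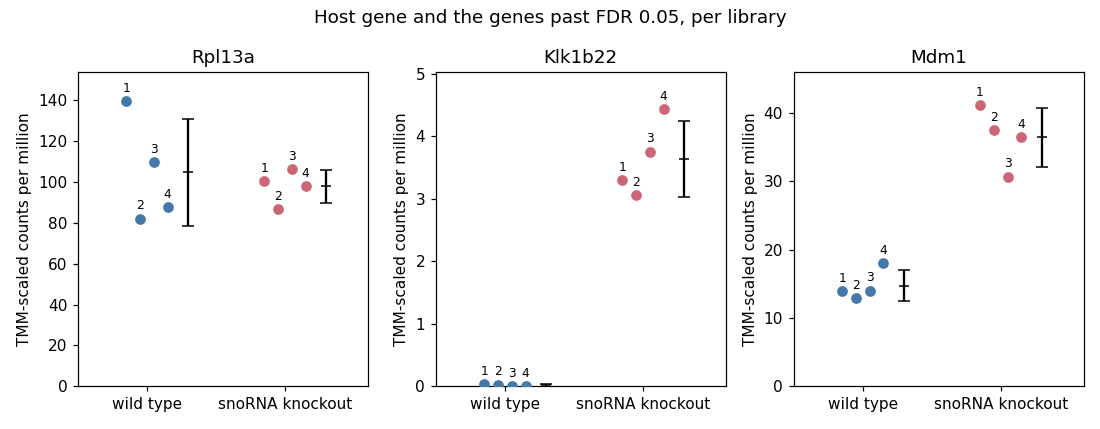
Each point is 1 library, labelled with its replicate number, and gives TMM-scaled CPM on a linear axis for Rpl13a, Klk1b22 and Mdm1; the bar beside each group is its mean with the SD (n = 4). The 4 knockout libraries lie between 3.06 and 4.43 CPM for Klk1b22, where wild type has 2 counts in all, and the genotypes overlap for Rpl13a.

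Klk1b22 and Mdm1 were the only genes of 13617 tested that passed FDR 0.05 in edgeR's quasi-likelihood test, and both rose in the knockout. Klk1b22 encodes a member of the kallikrein family of serine proteases. It had 56, 94, 85 and 138 counts in knockout replicates 1 to 4 and 2 counts over the 4 wild-type libraries (edgeR adjusted p = 2.0e-05). The ratio of the scaled counts was 236, with a 95% exact counting interval of 65.0 to 1958. Reads of Klk1b22 can be shared with its close paralogs, among them Klk1, which is abundant in exocrine pancreas, so its level is uncertain. In the GRCm38 annotation order Klk1b22 lies on chromosome 7, 42 tested genes from Rpl13a. Mdm1, which encodes a microtubule-binding centriole protein, was at 14.7 ± 2.26 CPM in wild type and 36.5 ± 4.34 CPM in knockout (n = 4 each). Its log2 fold change was 1.31 ± 0.13 (SE, edgeR adjusted p = 0.0030), and all 4 knockout libraries lay above all 4 wild-type libraries.

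The count of 2 genes depended on wild-type replicate 1: without that library 1313 of 13874 genes passed FDR 0.05, 470 higher and 843 lower in the knockout, and without knockout replicate 4 there were 5. With all 8 libraries 2545 genes had an unadjusted p under 0.05, against 681 that chance would give on average. The count was 721 with no composition factor, 780 with limma-trend and 1721 with the GC trend removed. It was 3841 with library weights and 3882 without wild-type replicate 1. The genotypes did not overlap for 1135 genes, or 8.34% of those tested, where chance gives 2.86% on average. Correlated genes widen the spread around both averages, and neither excess was set against other splits of the libraries.

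Among genes higher in the knockout that did not pass FDR 0.05, the smallest p-values belonged to Usp2, Noct, Pop4, Tsc22d3 and Nostrin. Usp2, a deubiquitinase gene under circadian control, had a log2 fold change of 1.51 ± 0.22 (SE, edgeR adjusted p = 0.0986), and Noct, the circadian gene for nocturnin, one of 1.16 ± 0.18 (adjusted p = 0.116). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was at 8.21 ± 1.53 CPM in wild type and 13.9 ± 0.75 CPM in knockout. Pop4, a subunit gene of ribonuclease P and MRP, had a log2 fold change of 1.64 ± 0.29, and Nostrin, a regulator of nitric oxide synthase traffic, one of 0.84 ± 0.16. Among genes lower in the knockout, the smallest p-values belonged to Srebf2, Plppr2, Fhdc1, Smim22 and Slc14a2. Srebf2, the transcription factor of cholesterol synthesis, was at 34.4 ± 4.56 CPM in wild type and 21.8 ± 0.67 CPM in knockout, a log2 fold change of -0.66 ± 0.11. The urea transporter gene Slc14a2 had a log2 fold change of -1.63 ± 0.26, Fhdc1 one of -0.78 ± 0.13, Plppr2 one of -0.69 ± 0.11 and Smim22 one of -0.59 ± 0.10. For each of these 10 genes all 4 knockout libraries lay on the same side of all 4 wild-type libraries. All except Usp2 had an edgeR adjusted p of 0.116.

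Beta-cell genes leaned lower in the knockout. In the list of beta-cell identity genes 23 of 29 members had a negative log2 fold change, with a median of -0.18. No member passed FDR 0.05 over all genes, while 11 were lower and 0 higher when adjusted over the list alone. Examples are Glp1r, the receptor of the incretin GLP-1, at 75.6 ± 16.7 CPM in wild type and 45.9 ± 2.91 CPM in knockout (log2 fold change -0.72 ± 0.15), and Ucn3, urocortin 3 of mature beta cells, at 300 ± 58.5 and 189 ± 11.1 CPM (-0.66 ± 0.14). Of list members picked after their values were seen, the insulin gene transcription factors Mafa and Pdx1 had log2 fold changes of -0.88 ± 0.22 and -0.44 ± 0.11, and Nkx6-1 had -0.43 ± 0.13. Genes of electrical excitability and exocytosis had 20 of 24 negative values and a median of -0.25, with 0 members past FDR 0.05 over all genes and 9 lower when adjusted over the list alone. Among them were Abcc8 (log2 fold change -0.60 ± 0.14) and Kcnj11 (-0.51 ± 0.12), which encode both subunits of the ATP-sensitive potassium channel. Both lie near the targeted locus on chromosome 7, Kcnj11 36 and Abcc8 37 tested genes from Rpl13a. Linkage to the targeted allele is thus open for these 2 genes. By contrast, genes that mature beta cells keep low or that mark dedifferentiation had 15 of 19 positive values and a median of 0.54. None passed FDR 0.05 over all genes or adjusted over the list alone, with Tgm2 at 0.57 ± 0.19 and Acot7 at 0.53 ± 0.18 as the members of smallest p. Camera with the preset correlation gave adjusted p-values of 0.00014 for identity, 0.0015 for excitability and 0.0061 for the disallowed genes. None of these calls held when the correlation was estimated (adjusted p = 0.696 for each) or in fry's directional test (adjusted p = 0.131, 0.299 and 0.131). Wild-type replicate 1 had a list median of -0.23 for identity, inside the knockout range, and of -0.35 for excitability, below all 4 knockout libraries. The excitability median was -0.40 without that library and -0.15 without wild-type replicate 2, and the identity median was -0.11 with the acinar share as a covariate. For the disallowed genes wild-type replicate 1 had 0.05 and all 4 knockout libraries lay between 0.28 and 0.62, highest in knockout replicate 2. The median log2 fold change of that list was 0.41 without knockout replicate 2 and 0.66 without knockout replicate 3. It was 0.43 with the acinar share as a covariate and 0.22 with limma-trend.

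**Figure D2:**
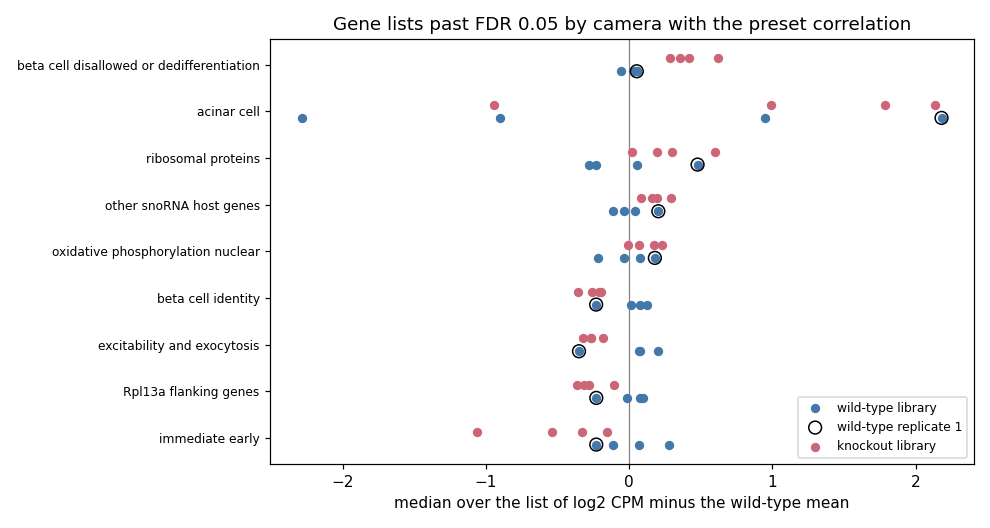
Each point is 1 library and gives the median, over the tested members of a gene list, of log2 CPM minus the wild-type mean of each gene; shown are the 9 lists past FDR 0.05 by camera with the preset correlation, of which 0 passed with an estimated correlation (lowest adjusted p = 0.696) or in fry's directional test. Wild-type replicate 1, ringed in black, lies among the knockout libraries for beta-cell identity (-0.23) and away from them for the disallowed genes (0.05).

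The remaining prohormone and islet cell lists did not pass. Of 19 genes of prohormone processing and the secretory granule, 3 were lower when adjusted over the list alone and 0 over all genes, and camera gave an adjusted p of 0.294. The granule protein gene Chga had a log2 fold change of -0.58 ± 0.14 and Resp18 one of -0.38 ± 0.10. Alpha-cell genes had 9 of 12 positive values (camera adjusted p = 0.351) and delta, PP and epsilon cell genes 10 of 11 (0.0865). Ttr, an alpha-cell gene that liver also expresses, had a log2 fold change of 0.38 ± 0.19, and of 0.14 without knockout replicate 2, the library with 1.14% of counts on liver genes. Etv1, from the list of delta, PP and epsilon cells, had one of 0.44 ± 0.15.

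The 6 islet hormone genes took 18.5 ± 6.05% of assigned counts in wild type and 11.9 ± 3.50% in knockout (n = 4 each). The difference of -6.65 percentage points had a two-sided exact permutation p of 0.114 (adjusted p = 0.571 over 10 shares). Ins2 alone took 12.6 ± 4.17% and 7.53 ± 2.19% (exact permutation p = 0.0857, adjusted 0.571). In the gene-level fit Ins2 had a log2 fold change of -0.58 ± 0.16 and Ins1 one of -0.38 ± 0.15, with edgeR adjusted p-values of 0.151 and 0.229. All 4 knockout libraries were below all wild-type libraries for Ins2, and 3 of 4 for Ins1. Iapp, the islet amyloid gene, had a log2 fold change of -0.17 ± 0.18. Gcg, Sst and Ppy, the glucagon, somatostatin and pancreatic polypeptide genes, had log2 fold changes of 0.24 ± 0.20, 0.18 ± 0.13 and 0.46 ± 0.51, and none of the 6 passed FDR 0.05 in edgeR's test of the 8 libraries. When each library was left out, the values ran from -0.27 (without wild-type replicate 1) to -0.047 (without knockout replicate 1) for Iapp and from 0.11 (without knockout replicate 4) to 0.36 (without knockout replicate 3) for Gcg. They ran from 0.095 (without knockout replicate 1) to 0.25 (without wild-type replicate 4) for Sst and from 0.22 (without knockout replicate 1) to 0.78 (without knockout replicate 3) for Ppy. Over 27 alternatives Ins2 passed in 3 and Ins1 in 1. One of those for Ins2 was the fit without wild-type replicate 1 (log2 fold change -0.69, edgeR adjusted p = 0.0142).

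Exocrine RNA varied widely between preparations. The 37 acinar genes took 29.2, 2.23, 15.7 and 5.36% of counts in wild-type replicates 1 to 4 and 24.2, 5.89, 30.8 and 19.5% in the knockout replicates. The group means of 13.1 ± 12.2% and 20.1 ± 10.5% differed by less than the spread between libraries (exact permutation p = 0.400, adjusted 0.679). In the list test 35 of 36 acinar genes had positive log2 fold changes with a median of 0.52, and camera gave an adjusted p of 0.0016 with the preset correlation. With an estimated correlation the adjusted p was 0.839, and without wild-type replicate 2, the library lowest in acinar RNA, it was 0.255 with the preset correlation. The call was also lost with DESeq2 (0.0537, with the median still at 0.52) and in the 5 libraries with low Xist (0.288). The median was 1.47 without wild-type replicate 1, 0.15 and 0.22 without wild-type replicates 2 and 4, and 0.32, 0.87 and 0.16 without knockout replicates 1, 2 and 3. Reg2 and Reg1, regenerating-islet genes of acinar cells, had log2 fold changes of 5.97 ± 1.97 and 1.91 ± 1.30, neither past FDR 0.05. Without knockout replicate 3, where both were highest, they were 3.73 and 0.72, and Reg1 was 3.59 without wild-type replicate 1.

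**Figure D3:**
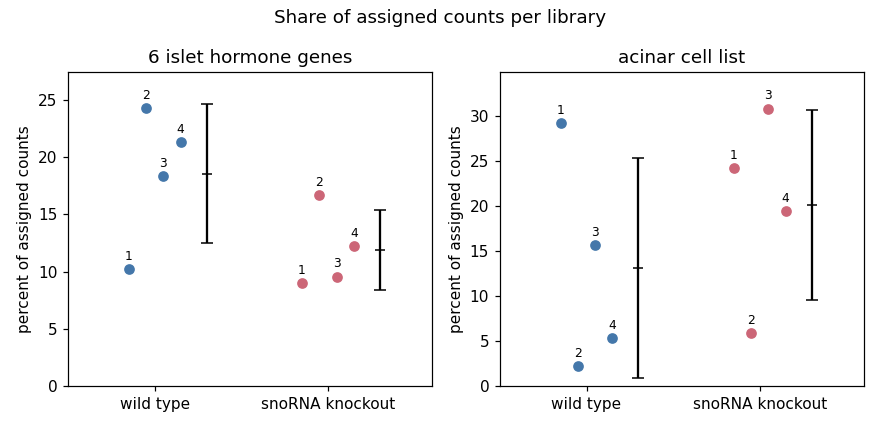
Each point is 1 library, labelled with its replicate number, and gives the percent of assigned counts in 6 hormone genes or in the acinar cell list; bars are group means with the SD (n = 4). Acinar shares run from 2.23 to 30.8% and overlap between the genotypes, and wild-type replicate 1 has the lowest hormone share of the wild-type libraries, 10.2%.

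Ribosomal protein genes had 65 of 78 positive log2 fold changes with a median of 0.24 (camera adjusted p = 2.9e-05 with the preset correlation). No member passed FDR 0.05 over all genes or adjusted over the list alone, and with an estimated correlation the adjusted p was 0.839. Rps21 had a log2 fold change of 0.72 ± 0.20 and Rps15a one of 0.57 ± 0.19. With the acinar share as a covariate the median was 0.053 (camera adjusted p = 0.261), and wild-type replicate 1, rich in acinar RNA, had a list median of 0.48. The median over the list was 0.40 without wild-type replicate 1, 0.14 without wild-type replicate 2 and 0.12 without knockout replicate 3. Host genes of other snoRNAs had 19 of 23 positive values and a median of 0.19 (camera adjusted p = 0.0228 with the preset correlation, adjusted p = 0.696 with an estimated correlation), among them Snhg6 at 1.31 ± 0.36 and Taf1d at 0.47 ± 0.15, with 0 members past either adjustment. That call was lost with the acinar covariate (adjusted p = 0.163, median 0.13), with DESeq2 (0.0672, median 0.18), without wild-type replicate 2 (0.106, median 0.11) and without knockout replicate 3 (0.0724, median 0.15); without wild-type replicate 1 the median was 0.31. Genes of snoRNPs and ribosome biogenesis did not pass (median 0.074, camera adjusted p = 0.294), with Utp20 at 0.40 ± 0.11 and Nop14 at 0.26 ± 0.10.

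Nuclear genes of oxidative phosphorylation had 50 of 76 positive values, a median of 0.088 and a camera adjusted p of 0.0157 with the preset correlation and an adjusted p of 0.839 with an estimated correlation. Adjusted over the list alone, 5 were higher and 1 lower, and 0 over all genes. Cox6c had a log2 fold change of 0.60 ± 0.13 and Uqcrfs1, the Rieske protein gene of complex III, one of 0.70 ± 0.16. The median was 0.14 without wild-type replicate 1. The list did not pass without wild-type replicate 2 (adjusted p = 0.382, median 0.020), knockout replicate 2 (0.0989) or knockout replicate 3 (0.0724). It also failed with the acinar share as a covariate (0.221), the replicate block (0.0537, median 0.089), no composition factor (0.132, median 1.7e-05) or limma-trend (0.0841, median -0.040). Antioxidant genes had 28 of 39 positive values (camera adjusted p = 0.0647). Gstm1 and Prdx1 had log2 fold changes of 1.05 ± 0.33 and 0.65 ± 0.22, and knockout replicate 2 held the highest count of both; without it they were 0.59 and 0.37. Genes of oxidases that make reactive oxygen species had 9 of 11 positive values (camera adjusted p = 0.111), with 2 higher when adjusted over the list alone. These were Rac1, a subunit of the NADPH oxidase complex, at 0.47 ± 0.12 and the xanthine oxidoreductase gene Xdh at 1.22 ± 0.36. Xdh was highest in knockout replicate 2, at 8.15 CPM against 2.52 to 5.78 CPM in the other knockout libraries. Its log2 fold change ran from 0.88 to 1.43 when each library was left out. Glycolysis genes had 14 of 19 negative values and 3 lower when adjusted over the list alone (camera adjusted p = 0.0708), including Pkm at -0.43 ± 0.11 and Eno2 at -0.52 ± 0.14; the median was -0.17 while the mean was 0.21.

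Immediate early genes had 16 of 21 negative values and a median of -0.50 (camera adjusted p = 0.0061 with the preset correlation, adjusted p = 0.696 with an estimated correlation). Only Egr3 was lower when adjusted over the list alone, with a log2 fold change of -1.41 ± 0.36. Nr4a1 had -0.92 ± 0.29, and from -1.08 to -0.57 when each library was left out. The median was -0.31 with the GC trend removed, and wild-type replicate 1, at -0.23, lay inside the knockout range of -1.06 to -0.16. Among other stress lists, the p53 targets, the unfolded protein response and the heat shock genes gave camera adjusted p-values of 0.159, 0.799 and 0.841. Trp53inp1, a p53 target, had a log2 fold change of 0.61 ± 0.13 and Ppp1r15a, the GADD34 gene of the unfolded protein response, one of -0.65 ± 0.13, while Herpud1 from the same list had 0.61 ± 0.25. Genes flanking Rpl13a had 24 of 30 negative values and a median of -0.27 (camera adjusted p = 0.0015 with the preset correlation, adjusted p = 0.696 with an estimated correlation). Adjusted over the list alone 3 were lower and 1 higher, and Scaf1 and Ap2a1 had log2 fold changes of -0.55 ± 0.14 and -0.56 ± 0.15. Wild-type replicate 1 had a median of -0.23 for this list, and with a GC trend removed from each library the median was -0.048 (camera adjusted p = 0.438).

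Apart from the acinar list, neither the tested lists of other cell types nor those of MHC class I presentation and the interferon response gave a call. Camera adjusted p-values were 0.0529 for endothelial genes (15 of 17 negative), 0.0574 for MHC class I presentation (8 of 11 negative), 0.159 for fibroblast, stellate and pericyte genes, 0.351 for the interferon response, 0.472 for macrophage genes, 0.748 for ductal genes, 0.799 for erythroid genes and 0.956 for Schwann and neural genes. The TCA cycle, circadian clock, cell cycle and growth hormone and prolactin response lists gave 0.650, 0.408, 0.684 and 0.684, and the sex-linked genes 0.583. For heat shock, macrophage and Schwann genes the median and the mean had opposite signs. Lists of lymphocytes, adipocytes, strain-variable genes, the Rpl13a locus and mitochondrially encoded genes had fewer than 5 tested members and were not tested as lists. Of 2 lymphocyte genes tested, the B-cell receptor gene Cd79a was lower when adjusted over the list alone, with a log2 fold change of -1.44 ± 0.43 (edgeR adjusted p = 0.161 over all genes). The medians of these 2 genes lay between -1.30 and -0.75 in the knockout libraries and between -0.26 and 0.17 in wild type. That gap rests on few counts. Coro1a, the other gene, had 2 to 20 counts a library and a log2 fold change of -0.37 ± 0.47. For Cd79a the genotypes overlapped: knockout replicate 1 had 1.88 CPM and wild-type replicates 1 and 3 had 1.86 and 1.62 CPM. Of 3 adipocyte genes, Fabp4 was higher when adjusted over the list alone (log2 fold change 1.14 ± 0.37, edgeR adjusted p = 0.188 over all genes).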

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

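Within each genotype, 99 reported measures were searched for a library far from the other 3 of its group, and 19 of 198 group tests found one (a gap to the nearest library above the 95% critical value of Dixon's test), where chance gives about 9.9. The tests of liver RNA, of a wrong label, and of Klk1b22 against its paralog and acinar RNA were chosen after the result was seen.

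In knockout replicate 2, genes of a liver list written after the pattern was noticed took 1.14% of counts, against 0.0018 to 0.0034% in the other knockout libraries. Albumin (Alb) stood at 2794 CPM there and at most 5.53 CPM in the other 7 libraries, and Apob at 509 and 0.51 CPM. The deletion as the cause is argued against by the other 3 knockout libraries, whose median log2 ratio of the 38 liver genes over wild type was 0.29. RNA of liver in that library remains as a candidate source: the liver list had a median log2 ratio of 9.35 over the other libraries, while intestine and kidney lists had 0 and a spleen list -0.20. Of the 38 genes, 6 had a median above 1 CPM over the other 7 libraries. Removing that library left 2 genes past FDR 0.05, and Mrc1, a macrophage gene also found in liver, stood apart there at 9.23 CPM against 0.59 to 1.45.

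Leaving out wild-type replicate 1 raised the number of genes past FDR 0.05 from 2 to 1313, and in 1 of 35 splits of the other 7 libraries, the real one, as many genes passed, with 53 the highest of the others. That library was picked because leaving it out raised the real count, a choice the other splits did not get, so chance is left open. A knockout library under a wild-type name is argued against by the targeted snoRNAs, with 7 counts in that library and 0 in each knockout library. Klk1b22 was at 0.033 CPM in that library and 3.06 to 4.43 CPM in the knockouts. That gene was called with the library counted as wild type, so it is weaker evidence. Sex of the mice is argued against by the 1153 genes left with Xist class as a covariate. Acinar RNA content and GC content bias may each account for many of the calls, since the 7 libraries gave 256 genes with the acinar share as a covariate and 230 with the GC trend removed. Genes lower in that fit averaged 55.7% GC and higher ones 44.6%, but acinar share and GC trend both differ between the genotypes in the 7 libraries, so the drop may also reflect overlap with genotype, and the snoRNA deletion stays open.

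Klk1b22 had 373 counts in knockout and 2 in wild type. Misassigned reads of Klk1 are argued against by the ratio of both genes, which varied 8.07-fold over the knockout libraries, and acinar RNA by the CPM of Klk1b22, which varied only 1.45-fold while the acinar share ran from 5.89 to 30.8%. A candidate explanation is a chromosome 7 segment carried along with the targeted allele: among the 199 tested genes nearest to Rpl13a, 7.54% had an unadjusted p under 0.01 with the GC trend removed, against 3.26% of the rest (two-sided Fisher's exact p = 0.0038, genes not being independent replicates). The genes nearest to Rpl13a also include Pop4, Ppp1r15a, Kcnj11 and Abcc8, so a carried segment is open for them too. A direct effect of the deletion on Klk1b22 is also open, since every knockout library carries the same allele.

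The other libraries far from their group are given as values. Dixon's test sets a gap against the range of the group, so a flagged gap can be small. Wild-type replicate 1 had 25.5 CPM of Ap2a1, 18.7 of Rps15a, 1409 of Reg1, 18.6 of Plvap and 9.72 of Dcn, and wild-type replicate 2 had 36.5 CPM of Pdx1. Wild-type replicate 4 had an Rn45s share of 38.9%, 586 CPM of Xist and 0 CPM of the Y-linked Kdm5d. Knockout replicate 1 had 25.7 CPM of Scaf1, 45.2 of Idh3g and 40.2 of Per1. Knockout replicate 3 had 0.044 CPM of Ghrl, which was 1 count, and 194 CPM of Reg2. Knockout replicate 4 had 246 CPM of Abcc8, against 264 to 267 CPM in the other knockout libraries. It also had 15.9 CPM each of Hbb-b2 and Hbb-bt, which had equal counts in every library.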

How the results depend on the processing

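Settings with a GC trend, Xist class, 5 or 6 libraries, other library sizes for ribosomal RNA, or 7 libraries with a further term were chosen after seeing the data. The count of 2 genes past FDR 0.05 stayed within 1.5 times in 22 of 31 alternatives. It was 48 with no composition factor, 525 with DESeq2's Wald test and 549 with limma-voom with library weights, and ran from 2 to 1313 when each library was left out; the cause was not tested for these tools. Without knockout replicate 2 and wild-type replicate 1 together it was 1296. With wild-type replicate 1 left out it was 256 with the acinar share as a covariate, 230 with the GC trend removed and 1153 with Xist class. DESeq2 gave Klk1b22 no adjusted p. Mdm1 was not past FDR 0.05 with no composition factor, with limma-trend or in the 5 libraries with low Xist.

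With the real grouping 2 genes and 9 lists passed, and chance cannot be excluded. Of 35 splits of the 8 libraries, 3 gave as many genes (highest other 170) and 23 gave as many lists (highest other 15). The real split is counted in both numbers. The split with 170 genes set wild-type replicate 1 with knockout replicates 2, 3 and 4. One with 143 genes set it with knockout replicates 1, 3 and 4. Both differ from the real grouping by an exchange of wild-type replicate 1 and 1 knockout library, and point to a structure of the samples. All splits except these and the real one gave 0 or 1 genes.

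The list count of 9 was 14 at FDR 0.10, 0 with an estimated correlation and 0 in fry's directional test, and 6 to 12 when each library was left out. The identity, excitability and disallowed lists passed camera in all 27 alternatives refitted for lists (highest adjusted p = 0.0117, 0.0204 and 0.0227). The highest was 0.382 for oxidative phosphorylation, 0.163 for snoRNA host genes, 0.288 for acinar, 0.261 for ribosomal protein and, with the replicate block and the GC trend removed, 0.672 for flanking and 0.0825 for immediate early genes. The acinar median reversed to -0.22 with the acinar share as a covariate, a result of that construction.

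The Rpl13a value, past no threshold, was 0.0032 with library weights, 0.0084 with the GC trend removed, 0.13 without knockout replicate 2 and wild-type replicate 1 together, and -0.20 to 0.057 when each library was left out; it was -0.25 with the acinar share as a covariate and -0.21 with limma-trend. In the 5 libraries with low Xist, Iapp was 0.052, Gcg -0.12, Ppy -0.23 and both Hbb genes -0.33; with Xist class both Hbb genes were -0.090, from -0.91 (without knockout replicate 4) to 1.43 (without wild-type replicate 4) when each library was left out, and Entpd4 was -0.014 with limma-trend. The cause was not tested. The acinar difference ran from 3.33 to 12.3 points and the hormone difference from -9.42 to -4.74 over single libraries left out. Without a composition factor the median gene moved to -0.11.

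Libraries with the same replicate number were taken to share only a number, since their deviations correlated at 0.018 over genes for replicate 1, and at 0.26, 0.21 and 0.22 for replicates 2 to 4. Wild-type replicates 2, 3 and 4 correlated best with the knockout of their own number and wild-type replicate 1 with knockout replicate 3, a hint from the data and not the design. With the replicate block 2 genes passed; with the block and the GC trend removed 2 passed, Rpl13a was 0.049, and immediate early genes (adjusted p = 0.0825, median -0.28) and flanking genes (0.672) did not pass. The block ended the call of oxidative phosphorylation (adjusted p = 0.0537), with a median of 0.089 against 0.088 without it. The targeted snoRNAs had 0 to 5 counts each a library, and the reason for these low counts was not tested.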

Other observations

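The test of the glucocorticoid genes and of the GC trend was set down before its result was seen, but both patterns were noticed in these data. In the 7 libraries without wild-type replicate 1, beta-cell identity had 11 of 29 members lower past FDR 0.05 and excitability 10 of 24 lower, with 0 higher in either. In that fit Glp1r had a log2 fold change of -0.87 ± 0.10 (edgeR adjusted p = 0.0056), Ucn3 -0.80 ± 0.10 (0.0059), Abcc8 -0.74 ± 0.09 (0.0053) and Ins2 -0.69 ± 0.13 (0.0142). Ribosomal protein genes had 21 of 78 members higher and 0 lower, and oxidative phosphorylation genes 13 higher and 1 lower. Fry's directional test then passed 7 lists, among them identity and excitability (adjusted p = 0.0034 each), while camera with an estimated correlation passed 0 (lowest adjusted p = 0.417). The library left out was known to raise the count, and acinar share and GC trend were not removed in this fit.

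Of 12 glucocorticoid-induced genes noticed in these data, 9 had higher values in all 4 knockout libraries than in any wild-type library, among them Rgs2 (log2 fold change 2.10 ± 0.33), Hif3a (2.31 ± 0.55), Usp2 (1.51 ± 0.22), Fkbp5 (1.05 ± 0.21), Klf9 (0.73 ± 0.15) and Tsc22d3 (0.76 ± 0.14), none past FDR 0.05 in edgeR's test with TMM on the 8 libraries. Per1 and Sgk1 had 2 of 4 knockout libraries above all wild-type libraries and Zbtb16 had 3. With DESeq2, with library weights and with no composition factor, Rgs2 and Usp2 passed on the 8 libraries; Usp2 also passed with no low-count filter and Rgs2 with limma-trend, and Tsc22d3 passed with DESeq2 and with library weights. All 12 were grouped after their values were seen. Usp2 and Tsc22d3 were also named by the rule as genes of smallest p. Per1 was named as a clock list member of smallest p. A hypothesis is a glucocorticoid or stress response at collection. A separate list of 20 such genes, written before their values were looked at, had a median log2 fold change of 0.41 over 19 tested members, 14 of them positive, but a camera p of 0.0710 with the preset correlation and a p of 0.303 with an estimated correlation, so the test did not decide.

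The lower values of genes flanking Rpl13a may come from GC content bias. These 30 genes averaged 57.5% GC against 49.7% over all tested genes, and with the GC trend removed their median log2 fold change was -0.048 in place of -0.27. The list then had an adjusted p of 0.438 in camera of limma with the preset correlation, so the call ended because the shift itself shrank. The GC trend itself differed between the genotypes. Per 10 points of GC, its log2 slope ran from -0.063 to 0.19 in wild-type libraries and from -0.17 to 0.0026 in knockout libraries. Removing it may thus also remove a genotype difference, so GC bias and genotype cannot be told apart here.

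By Xist and Y-linked counts, which the labels do not record as sex, wild-type replicate 4 and knockout replicates 1 and 4 had 20935, 11458 and 20491 Xist counts and 2 to 5 counts over 4 Y-linked genes. The other 5 libraries had 51 to 158 Xist counts and 1021 to 1526 Y-linked counts. Lyve1, a lymphatic and macrophage gene chosen after its values were seen, did not pass FDR 0.05 in the main fit (log2 fold change 1.48 ± 0.31, edgeR adjusted p = 0.117). It passed in 5 of 27 alternatives. One was the acinar share as a covariate (1.86, edgeR adjusted p = 0.0251), which gave its highest estimate.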
